A study of Homo sapiens with 12 samples.

How the data were processed

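RKO is a poorly differentiated human colon carcinoma cell line. Polyadenylated RNA was sequenced from 12 libraries of this line in 4 groups of 3. The titles give the groups only as NC, SH, Vec and OE. The series text names knockdown and overexpression of UBE2S, an E2 ubiquitin-conjugating enzyme that works with the anaphase-promoting complex. SH was read as the knockdown with NC as its control, and OE as the overexpression with Vec as its control. This reading was checked against the UBE2S counts of each library. No source says whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

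The deposited table holds raw whole-number counts per gene, with no normalization, for 20345 protein-coding gene entries, of which 4048 had no count in any library. Per the submitters' processing notes the genome build was hg19. The aligner, the counting program and the use of strand were not given in the sources used here, so reads of overlapping genes, antisense partners and near-identical copies may have been divided between them. Gene symbols and coordinates were taken from the table, and coordinates are hg19. Library totals ran from 48363231 to 82691351 counts. GC content and length came from the longest protein-coding transcript of each gene in GENCODE release 29, matched by gene identifier. They were found for 97.8% of the genes tested, and no coordinate of that build was used.

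Counts were fitted with edgeR 4.0.16 (R 4.3.3), with TMM normalization, the filterByExpr filter by group and a model of 4 group means over all 12 libraries. The filter left 13549 genes, which held 99.992% of the counts. Each contrast was tested with the quasi-likelihood test, and p-values were adjusted by Benjamini-Hochberg over all genes tested. A gene was called at an adjusted p under 0.05. The contrasts were SH vs NC, OE vs Vec, Vec vs NC, and the difference between the OE-Vec and SH-NC effects. The sum of these effects, which is 0 where they are equal and opposite, was added after the data were examined. The standard error of a log2 fold change was taken as its size divided by the square root of the test's F value. The biological coefficient of variation was 12.4%. Levels are given in CPM, the count scaled to a fixed library total with the TMM factors, as mean ± SD of 3 libraries.

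The 31 pathway and housekeeping lists and 3 lists of markers of other cell types were fixed before the data were examined. Of their 856 entries 854 matched the table, 24 of them by an older symbol. Pathway lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 31 lists within each contrast, and again with an estimated correlation. A list needed 5 tested members.

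The rule for named genes was fixed before the data were examined. It took UBE2S, the 8 largest called changes each way among genes with a mean of at least 5 CPM, a gene symbol that is not a clone name, and groups that did not overlap. It also took up to 3 called members of each called list, up to 6 genes called in opposite directions in each orientation, and a fixed set of genes given as values whether called or not. Not every list or gene of these sets is described. Called genes under 5 CPM numbered 223 in SH vs NC and 37 in OE vs Vec, and were counted but not named by that rule. Further list members are named as examples and were chosen after their values were seen.

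The alternatives fixed before the data were examined were DESeq2 size factors given to edgeR, no filter on low counts, the replicate number as a block, leaving out each library in turn, the Wald test of DESeq2 1.42.0, a fit of only the 6 libraries compared, the other control group, a minimum absolute log2 fold change of 1, and an estimated inter-gene correlation. A correction for GC content and length was added after seeing the data. It fitted a spline trend of each library's deviations on GC content and log length and gave it to edgeR as an offset. A pseudocount was not applicable because the table holds counts.

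The procedure was tested on simulated data drawn from the observed means, dispersions and library sizes, with 50 genes changed at each of 4 folds. For SH vs NC, with 13368 genes tested, 52% of the genes changed 1.3-fold and 84% of those changed 2-fold were recovered, and 6 of 13171 unchanged genes were called. For OE vs Vec, with 13375 genes tested, these shares were 54% and 72%, and 5 of 13179 unchanged genes were called. With the libraries' GC and length trends added to the simulated Vec vs NC data of 13377 genes, the uncorrected fit called 3109 of 13179 unchanged genes and the corrected fit called 14. For OE vs Vec these counts were 840 of 13148 and 9, and for SH vs NC 212 of 13179 and 16. The added trends had the form that the correction fits, so these counts do not show how it handles a trend of another form. A simulated shift of 1.3-fold in the heat shock list was called, with 0 of the other lists called by camera. Simulated genes were drawn independently, so this does not test how often camera calls lists of correlated genes. Counts of replicates differed by more than sampling noise in each pair, so no library was treated as deposited more than once. Figures were drawn with matplotlib 3.10.9.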

Results

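Gene expression was measured by RNA sequencing in 12 libraries of the RKO colon carcinoma line, 3 in each of the groups NC, SH, Vec and OE. Total counts per library ran from 53769036 to 68197413 in NC, 50878722 to 60184239 in SH, 48363231 to 70426136 in Vec and 56118744 to 82691351 in OE. OE replicate 3 stood apart from the other OE libraries, with a chi-square per degree of freedom of 35.7 and 43.4 against them, where the other pairs within groups gave 10.5 to 16.1. The stated purpose was to learn which signalling pathways respond when UBE2S is raised or lowered.

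UBE2S (ENSG00000108106, hg19 chromosome 19, 55912652 to 55919145) had 16352, 16290 and 12734 counts in the NC libraries and 2683, 2809 and 3248 in the SH libraries. It had 10837, 16778 and 11462 counts in Vec and 32101, 36706 and 45217 in OE. Its level was 244 ± 3.29 CPM in NC and 52.5 ± 1.76 CPM in SH (SD, n = 3), a log2 fold change of -2.22 ± 0.0557 (SE), with an adjusted p of 8.6e-13 by edgeR's quasi-likelihood test. In OE it was 563 ± 26.5 CPM against 218 ± 17.9 CPM in Vec, a log2 fold change of 1.37 ± 0.053 and an adjusted p of 6.12e-10. The exact two-sided permutation test gave p = 0.1 in each comparison, the smallest p that 3 against 3 libraries allow. The interval of UBE2S overlaps that of RPL28 in the table.

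**Figure D1:**
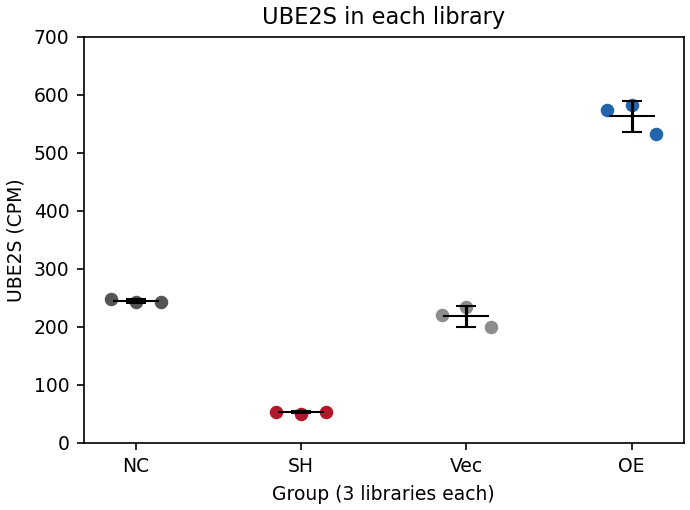
UBE2S level in CPM (vertical axis) in each of the 12 libraries by group (horizontal axis); points are libraries and bars the mean and SD of 3. SH averaged 52.5 CPM and OE 563 CPM, against 244 in NC and 218 in Vec.

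SH was compared with NC to find what changed with less UBE2S. Genes of the ATF4 and amino acid response, which supply cells with amino acids under stress, were lower in SH. Of 23 measured members 20 fell, 1 rose and 2 were not called. ASNS, which makes asparagine, fell by 1.54 on the log2 scale (SE 0.0864, adjusted p = 6.23e-09, edgeR), from 213 ± 33.4 to 73.3 ± 3.19 CPM (n = 3). SLC7A11, the cystine transporter, had a log2 fold change of -1.40 ± 0.0684, and PHGDH, the first enzyme of serine synthesis, one of -0.83 ± 0.0439. TRIB3, a pseudokinase induced by ATF4, was also lower at -1.03 ± 0.0731, and the ATF4 transcript itself at -0.34 ± 0.0438. ATF5 was the member that rose, at 0.44 ± 0.0823. The list median was -0.56, with a camera adjusted p of 3.72e-27 and an adjusted p of 0.021 with an estimated correlation. Adjusted over the list alone, 20 members were lower and 1 higher.

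Heat shock genes, which encode chaperones, rose in SH in 16 of 16 measured members, with a median log2 fold change of 0.43. HSP90AA1, an HSP90 chaperone, went from 1088 ± 56.6 to 1852 ± 97 CPM, a log2 fold change of 0.77 ± 0.0409. DNAJA1, an HSP40 co-chaperone, had a log2 fold change of 0.78 ± 0.0461, and HSPA1A, an HSP70, one of 0.98 ± 0.0567. HSPA1A is uncertain because its reads can be shared with the near-identical HSPA1B. The camera adjusted p of the list was 1.34e-26, and the adjusted p was 0.00399 with an estimated correlation. Proteasome subunits rose in 24 of 30 measured members and fell in 1. PSMC2 had a log2 fold change of 0.59 ± 0.0432 and PSMD14 one of 0.47 ± 0.0434; both are subunits of the regulatory particle, and PSMD14 was not called against Vec in place of NC (0.10, adjusted p = 0.0702). The proteasome list had a median of 0.32, a camera adjusted p of 2.6e-15 and an adjusted p of 0.0269 with an estimated correlation. Ribosome biogenesis genes and MYC targets rose in 21 of 26 members, with a median of 0.38 and adjusted p-values of 5.17e-17 and, with an estimated correlation, 0.00198. Among them NOP56, a nucleolar protein, had a log2 fold change of 0.51 ± 0.0392 and ODC1, an enzyme of polyamine synthesis, one of 0.41 ± 0.0305. Adjusted over the list alone, 16 heat shock, 25 proteasome and 23 ribosome biogenesis genes were higher.

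FOXO targets fell in SH in 13 of 17 measured members and rose in 1, with a median log2 fold change of -0.56. TXNIP, which restrains glucose uptake, fell from 177 ± 16 to 85.6 ± 1.2 CPM, a log2 fold change of -1.05 ± 0.0518, and ERBB3, a receptor of the EGFR family, had one of -0.80 ± 0.0516. The FOXO list had a camera adjusted p of 5.21e-08 and an adjusted p of 0.026 with an estimated correlation. YAP/TAZ targets fell in 10 of 15 members and rose in 1, with CRIM1 at -0.57 ± 0.0582 and AMOTL2 at -0.49 ± 0.0528. That list had adjusted p-values of 5.11e-05 and, with an estimated correlation, 0.0328, which became 0.0618 after the GC and length correction, with the median at -0.33 before and -0.29 after, 9 members still lower and a camera adjusted p of 0.000795. Wnt/beta-catenin targets fell in 7 of 16 members and none rose in the edgeR test. CD44, a cell surface receptor, had a log2 fold change of -0.77 ± 0.0502, CCND1, the cyclin D1 gene, one of -0.58 ± 0.0346, and AXIN2, a feedback inhibitor of Wnt signalling, one of -0.86 ± 0.15. The Wnt list had a median of -0.17 and adjusted p-values of 0.00098 and, with an estimated correlation, 0.0269. After the GC and length correction this list had a median of -0.09, with 6 members lower (camera adjusted p = 0.00505, and 0.0427 with an estimated correlation). It was also lower in Vec vs NC, in 5 of 16 members with a median of -0.19 (camera adjusted p = 0.0197, and 0.0882 with an estimated correlation). Adjusted over the list alone, 13 FOXO, 10 YAP/TAZ and 8 Wnt genes were lower.

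Lists called in SH only with the preset correlation were ERK output (12 of 19 lower, 2 higher), DNA double-strand break repair (11 of 26 higher, 2 lower), histone genes (4 of 13 lower), hypoxia targets (10 of 24 lower, 2 higher), glycolysis (8 of 18 lower, 1 higher), autophagy and lysosome (11 of 30 lower, 3 higher) and cytosolic ribosomal proteins (22 of 78 lower, 4 higher). With an estimated correlation their adjusted p-values were 0.177, 0.304, 0.297, 0.331, 0.385, 0.172 and 0.778 in that order. Except for hypoxia targets, these lists were also called in the same direction in Vec vs NC with the preset correlation. There ERK output was lower in 8 of 19 members and histone genes in 7 of 13. Glycolysis was lower in 13 of 18 and autophagy and lysosome in 12 of 30. Members higher there numbered 2, 0, 2 and 4, and the camera adjusted p-values were 0.0197, 0.0197, 0.000739 and 0.00845. With an estimated correlation none was called there. In SH vs NC, glycolysis (camera adjusted p = 0.327) and autophagy and lysosome (0.118) were not called after the GC and length correction. Histone genes were then called with an estimated correlation too (0.0324, 5 of 13 lower and 1 higher). Without NC replicate 3 the glycolysis list had a camera adjusted p of 0.0823 and the cytosolic ribosomal proteins one of 0.233, and without SH replicate 1 the latter had one of 0.0672. DNA replication and E2F targets were higher in 14 of 34 members and lower in 6 (camera adjusted p = 0.0562). That list was called without NC replicate 1, NC replicate 2 or SH replicate 2 (0.0209, 0.0376 and 0.0308) and after the GC and length correction (0.0396, and 0.527 with an estimated correlation). MDM2, a ubiquitin ligase, rose with a log2 fold change of 0.70 ± 0.0384 (0.40 against Vec), while CDKN1A, the p21 gene, was at -0.08 ± 0.044 (adjusted p = 0.183, edgeR). The anaphase-promoting complex list had 3 members higher and 3 lower of 18 (camera adjusted p = 0.411), and the mitosis list 10 higher and 3 lower of 32 (camera adjusted p = 0.145). CTNNB1, which encodes beta-catenin, was at -0.01 ± 0.0346, and the mitotic genes UBE2C and CDC20 were at 0.11 ± 0.0762 and 0.12 ± 0.0562, with ANAPC11 at -0.05 ± 0.082, none of them called by edgeR. CDC20 was called without SH replicate 1 (0.17, adjusted p = 0.0283), after the GC and length correction (0.18, adjusted p = 0.0133) and against Vec (0.25, adjusted p = 0.00235), and ANAPC11 against Vec (0.23, adjusted p = 0.0374). CCNB1, a mitotic cyclin, rose (0.32 ± 0.0393), and VHL, which targets HIF proteins for degradation, fell (-0.37 ± 0.0441), but was not called against Vec (-0.11, adjusted p = 0.0548). MYC was at -0.11 ± 0.0325 (adjusted p = 0.0122), and not called without SH replicate 3 (-0.08, adjusted p = 0.0576) or once corrected for GC content and length (-0.07, adjusted p = 0.053). Against Vec it was higher in SH (0.22, adjusted p = 5.56e-05), so its direction depends on the control.

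**Figure D2:**
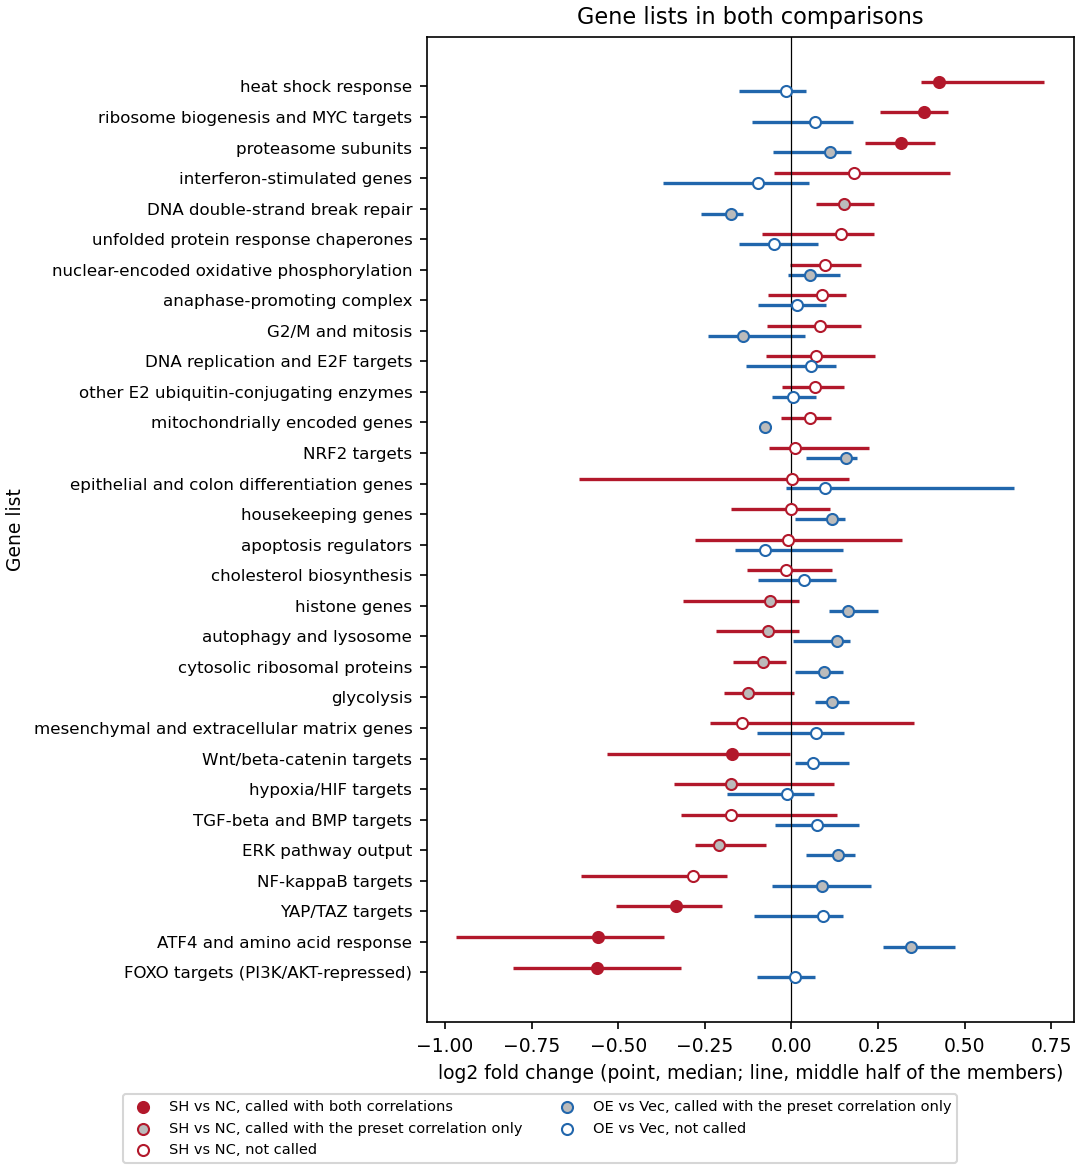
Median log2 fold change (horizontal axis) of gene lists (vertical axis) in SH vs NC and OE vs Vec; lines run from the first to the third quartile of the members and fill shows whether camera called the list. The heat shock list lies at 0.43 in SH vs NC, and the ATF4 list at -0.56 in SH vs NC and 0.34 in OE vs Vec.

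Besides UBE2S and ASNS, the largest decreases in SH were in PRSS8, a membrane serine protease (log2 fold change -1.88 ± 0.155), SMIM14 (-1.78 ± 0.167), SLC6A9, a glycine transporter (-1.62 ± 0.144), UNC5A, a netrin receptor (-1.56 ± 0.191), SERPINE2, a protease inhibitor (-1.51 ± 0.147), and AHNAK2 (-1.50 ± 0.136). The largest increases were in ARL2BP (1.32 ± 0.0462), LXN (1.17 ± 0.17), RGS4, a regulator of G-protein signalling (1.14 ± 0.152), C5orf15 (1.12 ± 0.0613), SEPT2, a septin (1.04 ± 0.0343), SEMA3C, a semaphorin (0.99 ± 0.196), NAA15, a subunit of an N-terminal acetyltransferase (0.99 ± 0.0468), and HSPA1A. Against Vec in place of NC, SEPT2 was at -0.02, NAA15 at 0.09 and LXN at 0.18 in SH, with adjusted p-values of 0.686, 0.156 and 0.419 (edgeR), so these 3 increases held only against NC. Against Vec, ARL2BP was at 0.27 and C5orf15 at 0.22, while RGS4 was at 1.03 and SEMA3C at 0.89. LXN, SEPT2, NAA15, SLC6A9 and UNC5A overlap other genes in the table, which makes their counts less certain.

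Against Vec, the following changes in SH kept their direction and their call by edgeR, but some were smaller. UNC5A was at -0.715, SLC6A9 at -0.97, PHGDH at -0.39, HSP90AA1 at 0.34, AMOTL2 at -0.255, CCND1 at -0.34, AXIN2 at -0.515, CD44 at -0.53 and PSMC2 at 0.42. PRSS8 was at -1.80, SMIM14 at -1.83, SERPINE2 at -1.61, AHNAK2 at -1.31, ASNS at -1.22, SLC7A11 at -1.85, TRIB3 at -1.145, HSPA1A at 1.40, DNAJA1 at 0.63, NOP56 at 0.48, ODC1 at 0.67, TXNIP at -1.08, ERBB3 at -0.77 and CRIM1 at -0.56.

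In all, 4839 of 13549 genes were called in SH vs NC by edgeR, 2326 higher and 2513 lower, and 184 of them had an absolute log2 fold change of at least 1, of which 139 were under 5 CPM. The median absolute log2 fold change of the called genes was 0.32. With the GC and length correction 4908 genes were called, 3824 of them also called before with the same sign. HIF1A, at 0.01 ± 0.0443 (adjusted p = 0.925), was at -0.14 after the correction (adjusted p = 0.0188) and at -0.37 against Vec (adjusted p = 9.67e-06).

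OE was compared with Vec to find what changed with more UBE2S. The ATF4 and amino acid response list was higher in OE, with 17 of 23 members called higher and none lower by edgeR, and a median log2 fold change of 0.34. SLC7A5, a transporter of large neutral amino acids, went from 552 ± 3.14 to 815 ± 7.21 CPM (n = 3), a log2 fold change of 0.56 ± 0.0324 with an adjusted p of 1.13e-07. Its partner SLC3A2 had a log2 fold change of 0.43 ± 0.0382, SESN2, a leucine sensor, one of 0.54 ± 0.056, and ASNS one of 0.57 ± 0.0836. With NC as the control, SLC7A5 (0.32) and SESN2 (0.74) were called, while SLC3A2 (0.00, adjusted p = 0.981) and ASNS (0.26, adjusted p = 0.0868) were not. In OE vs NC the list median was 0.21, with 8 members called higher and 1 lower (adjusted p = 0.124 with an estimated correlation). In OE vs Vec the camera adjusted p was 9.83e-25, and the adjusted p was 0.0706 with an estimated correlation. After the GC and length correction the median was 0.30, and the adjusted p with an estimated correlation was 0.0237. Adjusted over the list alone, 19 members were higher.

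With the preset correlation 15 lists were called in OE vs Vec, of which 14 are described here. With an estimated correlation the ATF4 list had the lowest adjusted p, 0.0706, so that no call was left. Of the others, glycolysis had 10 of 18 members higher before and 1 after the GC and length correction, ERK output 9 of 19 and 4, cytosolic ribosomal proteins 19 of 78 and 10, autophagy and lysosome 10 of 30 and 3, NRF2 targets 8 of 15 and 2, histone genes 4 of 13 and 2, and proteasome subunits 14 of 30 and 5. Their adjusted p-values with an estimated correlation were 0.152, 0.152, 0.736, 0.0833, 0.0833, 0.227 and 0.43 in that order. Housekeeping genes (5 of 12 higher before and 1 after the correction), nuclear-encoded oxidative phosphorylation (9 of 61 and 5) and NF-kappaB targets (3 of 17 and 2) were also called, with adjusted p-values of 0.1, 0.756 and 0.15 with an estimated correlation. Of these higher lists, the proteasome subunits had 5 members lower, autophagy and lysosome 3, NRF2 targets 2 and oxidative phosphorylation 2. Except for proteasome subunits, these higher lists were called lower in Vec vs NC with the preset correlation, so their increases may depend on the control. There glycolysis was lower in 13 of 18 members, NRF2 targets in 7 of 15 and NF-kappaB targets in 9 of 17. Histone genes were lower in 7 of 13 and housekeeping genes in 8 of 12. Members higher there numbered 2, 3, 1, 0 and 0. With an estimated correlation none was called there.

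DNA double-strand break repair genes were lower in OE in 12 of 26 members before and 1 after the correction, mitosis genes in 11 of 32 and 5, and mitochondrially encoded genes in 4 of 13 and 1. Their adjusted p-values were 0.123, 0.123 and 0.62 with an estimated correlation. The correction took the medians of break repair from -0.18 to -0.02, of mitosis from -0.14 to -0.04 and of glycolysis from 0.12 to 0.03, and the corrected medians of the 13 lists other than ATF4 ran from -0.04 to 0.09. Glycolysis, NF-kappaB targets and mitochondrially encoded genes were not called after it (camera adjusted p = 0.122, 0.0518 and 0.451), while the heat shock list (median -0.06, camera adjusted p = 0.0427, and 0.497 with an estimated correlation) and interferon-stimulated genes (median -0.07, 0.0489 and 0.125) were. PRKDC, the catalytic subunit of DNA-dependent protein kinase, had a log2 fold change of -0.38 ± 0.0381, which was -0.21 after the correction and 0.04 against NC (adjusted p = 0.57). TOP2A, a topoisomerase of dividing cells, had one of -0.38 ± 0.0452, and -0.18 after the correction (adjusted p = 0.0117), but it was higher in OE against NC (0.48, adjusted p = 8.04e-06). The housekeeping gene GAPDH was at 0.20 ± 0.0187 (adjusted p = 2.33e-05, edgeR), at 0.05 after the correction (adjusted p = 0.28) and lower against NC (-0.10, adjusted p = 0.00461).

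Single libraries decided 4 of the list calls in OE vs Vec. The cytosolic ribosomal proteins had a camera adjusted p of 0.0643 without OE replicate 1 and 0.0724 without OE replicate 2. Oxidative phosphorylation had 0.0753, 0.517 and 0.567 without Vec replicate 3, OE replicate 1 and OE replicate 2, NF-kappaB targets 0.0824 and 0.126 without Vec replicate 2 and OE replicate 3, and mitochondrially encoded genes 0.164, 0.113 and 0.394 without Vec replicate 1, Vec replicate 2 and OE replicate 3. OE replicate 3 went the other way in the first 2 of these lists. Its mean deviation from the mean of the 12 libraries was -0.37 for the ribosomal proteins, against 0.08 and 0.10 in OE replicates 1 and 2 and -0.16 to -0.09 in Vec. For oxidative phosphorylation it was -0.36, against 0.07 and 0.08 in OE replicates 1 and 2 and -0.14 to -0.07 in Vec. For mitochondrially encoded genes it was -0.24, against -0.07 and -0.05 in OE replicates 1 and 2 and -0.05 to 0.01 in Vec. OE replicate 3 also differed by transcript length. Across genes its deviation had a Spearman correlation with length of 0.27, against -0.19 and -0.14 in OE replicates 1 and 2. Whether this trend accounts for its list values was not tested.

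After UBE2S, the largest increases were in GTPBP6 (0.84 ± 0.193), GDF15, a stress-induced cytokine (0.81 ± 0.133), SLC6A9 (0.81 ± 0.139), DHRSX (0.73 ± 0.189), TMEM120B (0.70 ± 0.122), FZD8, a Wnt receptor (0.66 ± 0.168), and ABHD16B (0.65 ± 0.14). GTPBP6, DHRSX and KRT222 each appear in the table more than once under the same symbol, and ANKHD1-EIF4EBP3 is a read-through of neighbouring genes, so their reads may have been divided. The largest decreases were in KRT222 (-0.99 ± 0.18), STC1, a secreted glycoprotein (-0.77 ± 0.0569), ANKHD1-EIF4EBP3 (-0.77 ± 0.2), SLC18A2, a monoamine transporter (-0.71 ± 0.173), CEP152, a centrosomal protein (-0.69 ± 0.113), BMP2K (-0.65 ± 0.152), ZNF81 (-0.62 ± 0.145) and GPR155 (-0.60 ± 0.168). Once corrected for GC content and length, GTPBP6 (0.665 ± 0.198), ABHD16B (0.46 ± 0.137), FZD8 (0.55 ± 0.166), SLC18A2 (-0.57 ± 0.175), ANKHD1-EIF4EBP3 (-0.65 ± 0.204), BMP2K (-0.435 ± 0.15), ZNF81 (-0.42 ± 0.137) and GPR155 (-0.38 ± 0.17) were no longer called. Their values shrank in part while the SEs stayed about as large. With fewer genes called, a call after the correction also needed a larger value relative to its SE. By edgeR, TNPO2 at 0.13 ± 0.0443 was called before the correction (adjusted p = 0.0481), while GTPBP6 was not called after it (adjusted p = 0.073). The lost calls therefore do not show that a GC and length trend caused the changes of these genes. Against NC in place of Vec, GDF15 was at 0.09, SLC6A9 at 0.16 and TMEM120B at 0.39, with adjusted p-values of 0.77, 0.58 and 0.0724 (edgeR), and of these named increases only that of UBE2S was called against NC. STC1 stayed lower after the correction (-0.66, adjusted p = 1.35e-05) and against NC (-0.73, adjusted p = 1e-06), as did KRT222 (-0.90, adjusted p = 0.0102, and -0.89, adjusted p = 0.00857). GPR155 was not called without Vec replicate 1, 2 or 3 or OE replicate 1 or 2 (adjusted p = 0.0677, 0.0503, 0.054, 0.0528 and 0.08), ANKHD1-EIF4EBP3 without Vec replicate 1 (0.0794), nor DHRSX without Vec replicate 3 (0.0587).

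Among the genes given whether called or not, MDM2 was at -0.20 ± 0.0382 in OE vs Vec (adjusted p = 0.00283), at 0.03 after the GC and length correction (adjusted p = 0.802) and at 0.11 against NC (adjusted p = 0.12). HIF1A was at -0.27 ± 0.044 (adjusted p = 0.00104), and not called after the correction (-0.09, adjusted p = 0.306) or against NC (0.11, adjusted p = 0.175). MYC was at 0.19 ± 0.0325 (adjusted p = 0.00128), not called after the correction (0.085, adjusted p = 0.0782) and lower in OE against NC (-0.15, adjusted p = 0.0139). CDKN1A was at 0.19 ± 0.044 (adjusted p = 0.00799), but at 0.05 after the correction (adjusted p = 0.542) and 0.01 against NC (adjusted p = 0.945). VHL was at 0.14 ± 0.0439 (adjusted p = 0.0399), 0.18 after the correction (adjusted p = 0.0248) and -0.12 against NC (adjusted p = 0.117), and it was not called without Vec replicate 3, OE replicate 1 or OE replicate 2 (adjusted p = 0.0873, 0.0801 and 0.0739). AXIN2 (0.25 ± 0.148), ANAPC11 (0.16 ± 0.0823), CDC20 (0.11 ± 0.0562), CCNB1 (0.08 ± 0.0393), CCND1 (0.03 ± 0.0344), UBE2C (0.01 ± 0.0762) and CTNNB1 (-0.07 ± 0.0346) were not called by edgeR. Of these, ANAPC11 was called without OE replicate 3 (0.29, adjusted p = 0.0039), CCNB1 after the correction (0.16, adjusted p = 0.032) and CCND1 against NC (-0.21, adjusted p = 0.00169).

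In all, 2913 genes were called in OE vs Vec by edgeR, 1207 higher and 1706 lower, and 30 had an absolute log2 fold change of at least 1, of which 28 were under 5 CPM. After the GC and length correction 563 were called, 347 higher and 216 lower, of which 363 had been called before with the same sign. The share of called genes that were higher was thus 41.4% before and 61.6% after the correction, and it ran from 35.8% without OE replicate 1 to 54.4% without OE replicate 3, so the side with more called genes was not stable. Against NC in place of Vec 806 genes were called, and without OE replicate 1, Vec replicate 3 or Vec replicate 1 the count was 1660, 1755 or 1933.

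The control groups differed from each other although neither is named as a change of UBE2S. In Vec vs NC 5304 genes were called by edgeR, 2704 higher and 2600 lower, and UBE2S was at -0.17 ± 0.0523 (adjusted p = 0.0201). With the GC and length correction 2360 were called, 993 higher and 1367 lower, so the side with more called genes changed. Of these 2360 genes, 1668 had been called before with the same sign. Cytosolic ribosomal proteins were lower in Vec in 47 of 78 members (median log2 fold change -0.29), and in 40 after the correction (-0.15). DNA double-strand break repair genes were higher in 21 of 26 (0.35), and in 9 after it (0.125). Before the correction these lists had camera adjusted p-values of 3.22e-14 and 2.8e-09, and adjusted p-values of 0.417 and 0.0735 with an estimated correlation. The ATF4 list was lower in 10 of 23 members and higher in 3 (camera adjusted p = 0.00484, and 0.417 with an estimated correlation), and lower in 9 and higher in 2 after the correction (camera adjusted p = 0.00963). Levels followed the GC content of the genes differently in each group. The Spearman correlation across genes, which are not independent replicates, between GC content and a library's deviation from the mean ran from 0.43 to 0.56 in NC, -0.25 to 0.10 in SH, -0.59 to -0.47 in Vec and 0.13 to 0.34 in OE. Across genes the log2 fold change correlated with GC content at -0.32 in SH vs NC, 0.70 in OE vs Vec and -0.69 in Vec vs NC. Levels also followed transcript length. The Spearman correlation of length with a library's deviation ran from -0.27 to -0.17 in NC and -0.28 to -0.15 in SH. In Vec it ran from 0.41 to 0.46, and in OE from -0.19 to 0.27. Length correlated with the log2 fold change at -0.04 in SH vs NC, -0.42 in OE vs Vec and 0.44 in Vec vs NC.

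**Figure D3:**
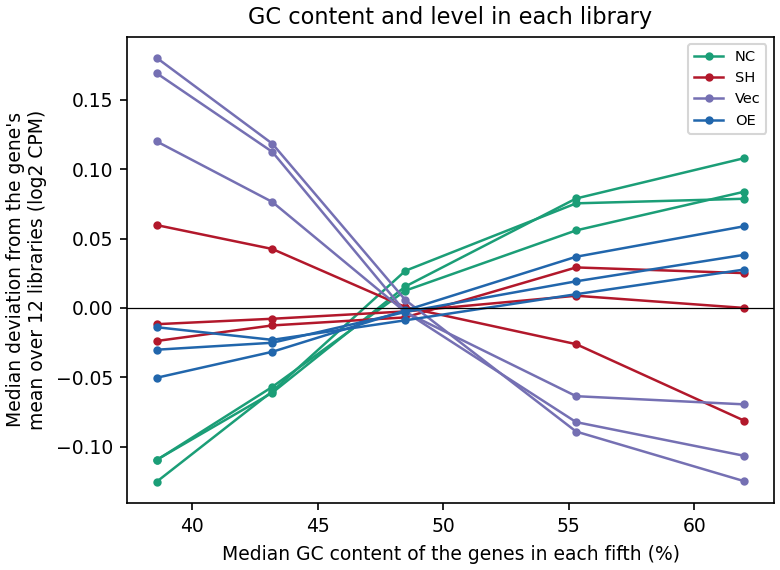
Median deviation of log2 CPM from each gene's mean over the 12 libraries (vertical axis) against the median GC content in percent of 5 equal groups of genes (horizontal axis), 1 line per library. The Vec libraries lie above OE among genes with a median GC content of 38.6% (median log2 fold change -0.19 for OE vs Vec) and below OE at 62% (0.14).

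SH vs NC and OE vs Vec share no libraries, and a gene that follows UBE2S in both would move in opposite directions. TRIB3, ASNS, SLC6A9, GDF15 and FZD8 were lower in SH and higher in OE. UTP20, a ribosome biogenesis factor, was higher in SH (0.71 ± 0.0522) and lower in OE (-0.53 ± 0.0521), as were ZNF823, DZIP3, DHX57, USPL1 and HMGN3. In OE vs Vec, FZD8 (0.66 before and 0.55 after, adjusted p = 0.0799), ZNF823 (-0.54 and -0.44, 0.161), DZIP3 (-0.47 and -0.28, 0.263) and USPL1 (-0.465 and -0.33, 0.116) were not called after the GC and length correction, though part of each change stayed, and UTP20 was at -0.33. Without single libraries of OE vs Vec, ZNF823 lost its call without Vec replicate 1, Vec replicate 3 or any of OE replicates 1 to 3 (adjusted p = 0.109, 0.0962, 0.0958, 0.0568 and 0.0779), DZIP3 without Vec replicate 1, Vec replicate 3 or OE replicate 1 (0.0701, 0.0955 and 0.0904), and USPL1 without Vec replicate 3 or OE replicate 2 (0.0688 and 0.0656). In SH vs NC it was DZIP3 that lost its call without NC replicate 2 or SH replicate 2 (0.0718 and 0.0514). With the control groups exchanged, TRIB3 was at -1.15 in SH against Vec and 0.75 in OE against NC, while ASNS was at -1.22 and 0.26, SLC6A9 at -0.97 and 0.16, UTP20 at 0.155 and 0.03, GDF15 at 0.09 and 0.09, and FZD8 at 0.07 and -0.10. So exchanged, ZNF823 was at 0.18 and -0.08, DZIP3 at -0.25 and 0.235, DHX57 at -0.12 and 0.11, USPL1 at -0.04 and 0.03, and HMGN3 at 0.275 and -0.27. Of the genes named here, TRIB3 was called in both exchanged comparisons, while the others were not called in OE vs NC by edgeR.

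In the ATF4 list 15 of 23 members were called lower in SH and higher in OE, and 14 after the GC and length correction. Over all genes 1147 were called in both comparisons in opposite directions, against 517 for independent lists of these sizes, and 388 in the same direction, against 524. Of the former, 483 were lower in SH and higher in OE (224 for independent lists), and 664 were higher in SH and lower in OE (293). After the GC and length correction the counts were 240 opposite (101 for independent lists) and 93 in the same direction (103). Without OE replicate 1, Vec replicate 3 or Vec replicate 1 the opposite count was 701, 733 or 751. The correlation of log2 fold changes across genes was -0.06 (Pearson, SE 0.076 from leaving out single libraries) and -0.17 (Spearman, SE 0.0481), and with the GC and length correction -0.03 and -0.06. These SEs treat the 12 libraries as 1 sample and do not take account of the 4 groups, so they are rough. Set against these SEs of the uncorrected values, the Pearson value and both corrected values lie within 2 SE of 0. The effects differed between the comparisons in 4865 genes by edgeR.

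**Figure D4:**
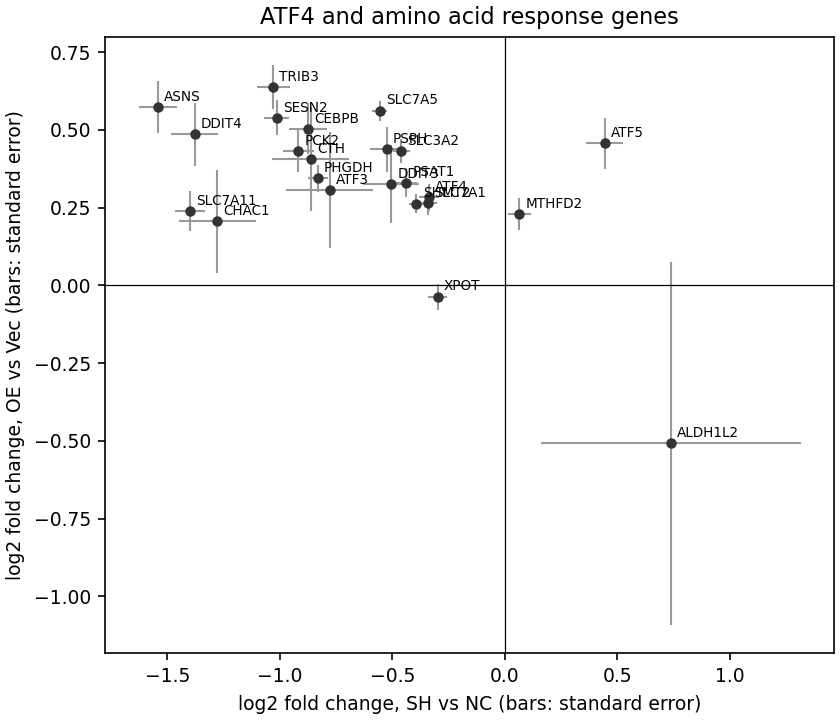
Log2 fold change of 23 genes of the ATF4 and amino acid response in SH vs NC (horizontal axis) and OE vs Vec (vertical axis), with standard errors as bars. In 19 of 23 genes the value was below 0 in SH vs NC and above 0 in OE vs Vec.

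Markers of other cell types were near the floor, with exceptions. Of 13 blood cell markers 1 had a mean above 1 CPM, CD68, a lysosomal protein also made by many cell lines, at 607 CPM. Of 8 endothelial markers the highest was ESAM at 7.67 CPM, and of 10 fibroblast markers COL1A1 at 1.79 CPM. In SH vs NC the lowest adjusted p among the markers tested was 0.0826 (CD68, edgeR), and in OE vs Vec ESAM was called (0.39, adjusted p = 0.0293).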

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

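The tests of GC content and of the summed BIVM-ERCC5 counts were chosen after the results were seen; those of library depth, of OE against NC and of the most variable genes were written before. The test of GC content as the whole cause was changed 2 times with the corrected counts known. Its bounds on the corrected count first differed between the 2 comparisons, at 1% for OE vs Vec and 5% for Vec vs NC, and were then shared. It now uses the genes called both before and after correction, because the corrected count alone does not show whether the same genes were called. For OE vs Vec the first and the present version argue against a trend of the form corrected for as the whole cause. The shared bounds did not decide. The present version is weak, since a gene still called after correction would tend to keep its sign.

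The heat shock, proteasome and ribosome biogenesis lists departed from a mirror image between the knockdown and the overexpression. The test was of the sum of the SH-NC and OE-Vec effects, which is 0 where they are equal and opposite; it was chosen after the data were examined. These lists passed it with both correlations and with and without the GC and length correction. The heat shock list had a median of 0.449 in that sum, the proteasome list one of 0.357 and the ribosome biogenesis list one of 0.309. These lists rose in SH, and OE did not show an opposite change of the same size. Proteasome subunits were also higher in OE, in 14 of 30 members, with 5 lower. Other lists were called in the sum too with the preset correlation. FOXO targets had a median of -0.587 (adjusted p = 0.0178 with an estimated correlation, and 0.0508 after the GC and length correction). The ATF4 list had a median of -0.334 (camera adjusted p = 0.000152, and 0.348 with an estimated correlation). Its opposite changes were thus not shown to be equal in size. No group of 4 or more samples existed for a test of single outlying samples.

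The first pattern is the large number of genes called between the control groups and in OE vs Vec. Library depth was argued against, since 5392 genes were called in Vec vs NC with every library thinned to the smallest total. As the whole cause a GC and length trend of the form that the correction fits was argued against in both comparisons. In Vec vs NC 1668 of 5303 called genes kept call and sign after correction, and in OE vs Vec 362 of 2912, UBE2S aside. In simulated data with that trend the corrected fit called 14 and 9 unchanged genes. The kept genes were 70.7% and 64.4% of those called after correction. Those shares decide little, since a gene still called would tend to keep its sign. A trend of another form stays open. As part of the cause the trend has the values it needs, Spearman correlations with GC content across genes of -0.69 and 0.7. In OE vs Vec 2548 genes lost their call. Their median absolute log2 fold change went from 0.23 to 0.08, while the median SE went from 0.0557 to 0.0503. These genes were picked by that loss, so their smaller changes are no evidence for the trend. In genes that kept their call the median went from 0.27 to 0.22. The share of the trend, a batch shared by the Vec libraries, a response to the vector and the change of UBE2S stay open, since the labels give no batch.

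The second pattern is the ATF4 list, lower in SH and higher in OE. A GC and length trend of the form that the correction fits was argued against by the corrected median in OE vs Vec of 0.30, by a rule written after the data were seen. For this list too a trend of another form stays open. A low level in the Vec libraries alone was argued against by OE against NC, where the list median was 0.213 (camera adjusted p = 2.97e-12), although the adjusted p was 0.124 with an estimated correlation and 8 of 23 members were called higher and 1 lower. As part of the cause a low level in Vec stays open, since the list was lower in Vec vs NC (camera adjusted p = 0.00484, and 0.417 with an estimated correlation). A response of the ATF4 program to the level of UBE2S may account for it, as may a difference in medium or cell density between cultures, which the labels do not record.

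The third pattern is a set of counts that switch between libraries of one group. BIVM-ERCC5, a read-through of 2 neighbouring genes, had 0 counts in 7 of 12 libraries and up to 42.5 CPM in the rest. Summed with BIVM and ERCC5, its CPM varied by 12.72% (coefficient of variation) against 124% alone, which is consistent with reads moved between overlapping gene models. Among the 50 genes with the highest dispersion 34% were read-through or repeated names, against 1.02% of the 10678 genes compared. A biological switch was not tested.

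The splits of the 6 libraries of a comparison number 10, the real one included, too few for a share under 0.05. In SH vs NC 1 split (the real one, 4761 genes in the fit of 6 libraries) reached that count and the highest other gave 2, in OE vs Vec 1 (2704, highest other 2) and in Vec vs NC 1 (5512, highest other 2). For gene lists with the preset correlation the real splits gave 15 and 13 lists and the highest others 10 and 7, so that correlation calls lists in splits where almost no gene is called. Over 100 of the 200 splits within both comparisons, 1, the real one, gave as many genes with different effects (4865, highest other 2147). A split not drawn, with OE and Vec exchanged, amounts to the sum of the effects, which called 3178 genes. Since the libraries of a group may be technical replicates, these splits cannot exclude a chance difference between cultures. For genes called in opposite directions 1 split, the real one, gave as many (1147, highest other 1). The other splits drawn call almost no gene in at least 1 of the comparisons. This bears on the number of calls and not on whether directions oppose.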

How the results depend on the processing

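The GC and length correction was added after seeing the data; the other settings were chosen before. UBE2S kept its direction and its call under each setting run, at -2.05 in SH against Vec, 1.203 in OE against NC, and from -2.24 to -2.19 in SH vs NC and 1.33 to 1.45 in OE vs Vec when single libraries were left out. Counts of genes stayed within 1.5 times under DESeq2 size factors, no filter, the DESeq2 Wald test, the fit of 6 libraries and, for SH, Vec as control (5669). With a minimum absolute log2 fold change of 1 the counts were 184 (SH vs NC) and 30 (OE vs Vec), by construction. Against NC, OE gave 806 genes in place of 2913. With the GC and length correction OE vs Vec gave 563, Vec vs NC 2360, opposite calls 240 and the Spearman correlation -0.0601; it was -0.12 with no filter. HIF1A in SH vs NC went to -0.144 and MDM2 in OE vs Vec to 0.027 with that correction. The share of higher calls in OE vs Vec was 41.4%, and 61.6% after it. With an estimated correlation 7 lists were called in SH vs NC in place of 14, and 0 in OE vs Vec in place of 15. The cause of these changes was not tested beyond the GC trend itself.

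Leaving out single libraries gave 4119 to 5019 genes in SH vs NC, 1660 to 3194 in OE vs Vec, 4421 to 5619 in Vec vs NC, 4305 to 4899 with different effects and 701 to 1161 called in opposite directions. The Pearson correlation ran from -0.10 to -0.01 and the Spearman correlation from -0.18 to -0.12. Lists called ran from 12 to 15 in SH vs NC and 13 to 15 in OE vs Vec. Of the lists, 13 results lost and 4 gained their call, and of the named genes 30 and 2. The cause was not tested.

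The replicate numbers did not pair the libraries. Correlations of same-numbered deviations ran from -0.059 to 0.014, and 2 of 12 libraries correlated best with their own number. With the replicate block 4820, 2936, 5282 and 4855 genes were called in SH vs NC, OE vs Vec, Vec vs NC and the difference, 1142 in opposite directions, UBE2S was at -2.22 and 1.37, and the block changed no list call. A pseudocount was not applicable to counts. Called genes with an absolute log2 fold change of at least 1 were mostly under 5 CPM. Those numbered 139 of 184 in SH vs NC and 28 of 30 in OE vs Vec. With every library thinned to the smallest total, 4796 and 3044 genes were called in these comparisons. Whether depth limits genes with few counts was not tested.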

Other observations

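The lists in this part were chosen after the main results were seen; the tests of the tRNA synthetases and of the CCT subunits were written before their values were seen. For the synthetases, the rule that a miss smaller than the quartile range of the members decides nothing was added afterwards.

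Subunits of the CCT chaperonin, which folds actin and tubulin, rose in SH in 7 of 8 members. CCT2 had a log2 fold change of 0.59 ± 0.0362 (adjusted p = 1.36e-08, edgeR) and CCT5 one of 0.46 ± 0.0306. The camera adjusted p was 1.05e-07, and the adjusted p was 0.0184 with an estimated correlation. Receptors of nuclear import and export rose in SH in 13 of 21 members and fell in 1, with XPO4 at 0.46 ± 0.0514 and CSE1L at 0.34 ± 0.0404, but the adjusted p with an estimated correlation was 0.272. The same list was higher in 14 of 21 members in Vec vs NC, with an adjusted p of 0.406 with an estimated correlation, and in 3 after the GC and length correction, with 3 lower (camera adjusted p = 0.981). In OE vs Vec 12 of the 21 were lower and 1 higher by edgeR, with an adjusted p of 0.257 with an estimated correlation and a camera adjusted p of 0.864 after the GC and length correction. Mitochondrial ribosomal proteins rose in SH in 17 of 34 members and fell in 2 (adjusted p = 0.272 with an estimated correlation). In Vec vs NC 17 of the 34 were lower and 0 higher, and in OE vs Vec 8 were higher and 0 lower. The adjusted p-values there were 0.406 and 0.332 with an estimated correlation.

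A hypothesis was that the higher heat shock genes in SH reflect heat shock factor activity that may also reach the CCT subunits. Their median of 0.35 in SH vs NC was above the bound of 0.1 set for it. Nuclear import and export receptors (0.23), mitochondrial ribosomal proteins (0.135), proteasome subunits (0.32) and ribosome biogenesis genes (0.38) were above it too. Passing the bound therefore does not single out heat shock factor activity, and the hypothesis stays open.

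A further hypothesis was that ATF4 activity may lower the cytosolic tRNA synthetases in SH and raise them in OE, apart from the mitochondrial ones. The predicted difference was not found in SH, and by the rule written before, this outcome counts against the hypothesis. The medians lie near 0 over members that go both ways, so by the rule added afterwards the test does not decide. In SH vs NC the median of the 20 cytosolic genes lay 0.08 above that of the 17 mitochondrial genes, in the direction opposite to the one predicted, and in OE vs Vec it lay 0.115 above, in the predicted direction. In SH vs NC the median of the cytosolic genes was 0.10 while camera gave the direction down (adjusted p = 0.107), so these differ in sign. In OE vs Vec 10 of the 20 were higher and 2 lower (camera adjusted p = 1.37e-05, and adjusted p = 0.049 with an estimated correlation). The quartiles of the cytosolic genes in SH vs NC were -0.29 and 0.185; 9 fell, 10 rose, and 9 of the 9 that fell also rose in OE by edgeR, against 7 of 9 after the GC and length correction, which left 7 of the 20 higher in OE. SARS, the seryl-tRNA synthetase, was at -0.60 ± 0.0384 in SH and 0.35 ± 0.0382 in OE, while RARS, the arginyl-tRNA synthetase, was at 0.56 ± 0.0619 in SH. Of the mitochondrial genes 2 fell in SH and 1 of these rose in OE. The split within the cytosolic genes was seen after the test and has no test of its own.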
